A study of Mus musculus with 65 samples.

How the data were processed

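Patch-seq libraries of 65 single mouse cells, 1 library per cell, were made with a 3' SMART-Seq kit without molecular identifiers and with Nextera XT. Per the submitters' processing notes, reads were mapped with STAR to mm10 and counted with HTSeq, without versions given. The deposited values are log10 residuals: the authors took log10 of 1 plus scaled counts, centred each of the 10407 genes over the 65 cells and removed 2 further directions over cells by regression. This description of the log10 values as deposited came from the values themselves. The removed directions held 24.2% of the variance of E12 membership, 8.81% of E15 membership and 3.31% of transplanted membership, 74.5% of that of genes detected and 41.3% of that of log10 total reads.

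The design had assumed counts, so read counts were recovered from the log10 residuals. For 9935 genes the plane of cells at 0 gave the removed part, and for 472 genes a search for values that make all counts whole did. All 356667 non-zero values lay within 0.01 of a whole number (largest distance 1.86e-09), and 0 genes were ambiguous. Every gene had a read in at least 6 cells, so genes seen in fewer cells were not used here. On simulated data the recovery returned 100% of 3851 genes, among them 40 with a read in at least 62 cells.

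Groups were taken from the labels as E12 FlashTag (20 cells), E15 FlashTag (26 cells) and E15 in E12 (19 cells). Labels also give 8 pools, A to H, whose meaning is not defined there. No animal is named, so no test between groups was made. Counts of a group were added and scaled to CPM by the sum over the genes in the tables, with a pseudocount of 1 CPM for log2 ratios. Intervals were exact Poisson limits for counts, exact binomial limits for shares and conditional binomial limits for ratios. A group at 0 was set to a floor of 3 counts over the group for a lower bound. Genes of lists needed 5 CPM in either group, and a list's median log2 ratio was placed among 10000 random lists matched in 20 expression bins. The 33 lists were written before the data were examined, as were the rule for named genes and the main alternatives. The pericyte and Cajal-Retzius lists had no gene in the tables.

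Named genes were chosen by rule in each comparison and direction. A gene needed at least 20 CPM and detection in at least 30% of cells in the higher group, a log2 ratio of at least 1 in size on summed and on mean CPM, and the same direction in at least 75% of pools. The 10 with the largest log2 ratio left after leaving out any cell were taken, passing over predicted genes. For each list, up to 2 members with the highest CPM and up to 2 with the largest ratio were added. Coordinates are GRCm38 in GENCODE vM21, found for 232 of 234 named symbols.

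The position took 200 genes per direction, detected in at least 25% of cells. They were chosen in E12 and E15 cells of pools A to D and measured in those of E to H, and the reverse. The transplanted level took all transplanted cells each time. A position was given only where the held-out difference was at least 0.5, a limit set after the E12-high value had been seen. Nearer profiles used means of 15 cells over 100 draws and genes in at least 20% of cells (10224 genes), leaving out the cell itself. Where a group had fewer than 15 cells left, both means took that smaller number. The genes used were 7958 without libraries above 8000 genes and 7454 without those above 7000 genes. The relation of ratios used 100 splits of the E15 cells. On simulated data genes raised 4 times gave medians of 1.93 to 2.02 and genes lowered 4 times -1.89 to -1.99. Simulated positions of 0, 0.5 and 1 returned 0.05, 0.53 and 1.04 for E15-high genes and -0.05, 0.48 and 0.98 for E12-high genes.

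Alternatives were mean CPM per cell, counts thinned to 28614 reads per cell, TMM and median-of-ratios factors computed with own code, totals without ribosomal and mitochondrial genes, filters of 1 count and 20 CPM, and pseudocounts of 0.1 and 5 CPM. Further ones left out each cell, each pool or the 10 cells under 57337.25 reads, or took the mean of ratios within pools. Positions were also made with 100 and 500 genes and with 100 random splits, and profiles with 10 cells, with genes in 50% of cells and with rank correlation. Leaving out libraries above 8000 genes was added after the per-cell levels of marker genes had been seen, and limits of 7000 and 9000 genes were tried after that, as were sums without the library that held most reads of a list or gene. The median log2 ratio of all genes was -0.03, -0.08 and -0.09 in the 3 comparisons over all cells. It was -0.16 on thinned counts in transplanted over E15 cells. Without the libraries above 8000 genes it was -0.01 for E15 over E12, -0.13 for transplanted over E15 and -0.16 for transplanted over E12. On mean CPM without these libraries it was -0.12, -0.003 and -0.13. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9 were used.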

Results

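Messenger RNA was sequenced from 65 single cells of CD1 mouse embryos, 1 library per cell, by Patch-seq, in which the content of a cell is drawn into a pipette. FlashTag, a fluorescent dye given into the ventricle, marks progenitors that divide at the ventricular surface. The libraries fall into 20 FlashTag cells of embryonic day 12 (E12), 26 FlashTag cells of embryonic day 15 (E15) and 19 E15 progenitors that had been placed in an E12 host brain, called transplanted cells here. The labels name no animal, litter or host, so each group counted as 1 sample and no p-value or standard error was made from cells. Expression is given as CPM, counts scaled by the total over the genes measured, from the reads of a group added up. Bounds in parentheses are exact 95% Poisson or binomial limits. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

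E12 cells held 10928 to 1635767 reads (median 148824), E15 cells 11449 to 4560871 (median 998630) and transplanted cells 22358 to 3622411 (median 166134). The sums were 4942302, 37479005 and 12716263 reads. The deepest cell held 33.1% of the E12 reads, 12.2% of the E15 reads and 28.5% of the transplanted reads; without the libraries above 8000 genes described below, the E15 and transplanted shares were 26.7% and 55.7%. The median cell had reads of 3748.5 genes at E12, 7497.5 at E15 and 5035 in the transplanted group. At an equal depth of 28614 reads the medians were 3039, 5241.5 and 4225 genes, over the 17, 24 and 17 cells with that many reads.

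Above 8000 genes were detected in 16 libraries, 11 of the 26 E15 cells (42.3%, 23.4 to 63.1), 5 of the 19 transplanted cells (26.3%, 9.15 to 51.2) and 0 of the 20 E12 cells (at most 16.8%). These 16 libraries, called many-gene libraries here, held 34531254 of the 55137570 reads. Most of them carried high levels of genes of cell types other than cortical progenitors: the median sum of 12 ventral telencephalon and interneuron genes was 3434 CPM against 60.7 CPM in the other libraries of the same pools. The sum of 13 microglia and macrophage genes was 2218 against 83.6 CPM, with a median of 3366 CPM in the 11 E15 libraries and of 29.5 CPM in the 5 transplanted ones. That of 20 apical progenitor genes was 3012 against 12024 CPM. The limit of 8000 genes was set after these levels had been seen, and values without the 16 libraries stand beside the list medians and beside part of the single genes. Sums without the library that held most reads of a list or gene were made after the data had been seen.

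**Figure D1:**
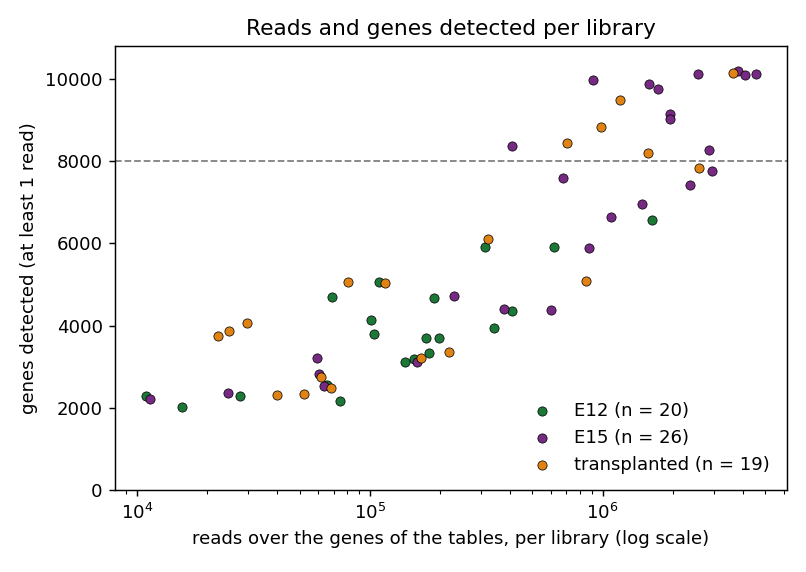
Genes detected per cell against reads per cell (log axis) in the 3 groups, with a dashed line at 8000 genes. The median was 148824 reads in E12 cells, 998630 in E15 cells and 166134 in transplanted cells.

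**Figure D2:**
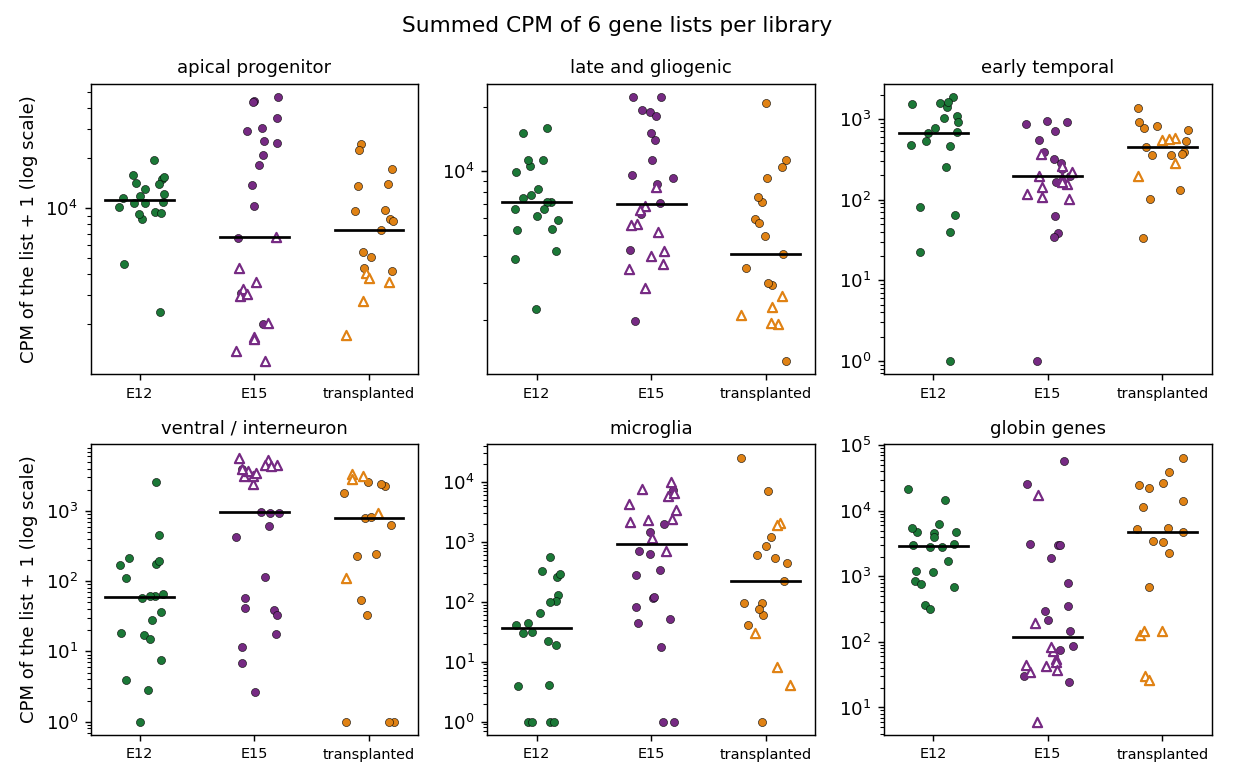
Summed CPM of fixed gene lists in each of the 65 cells, by group, with triangles for the 16 libraries above 8000 genes and lines for the medians. The median ventral telencephalon and interneuron sum was 3434 CPM in these 16 libraries.

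The E15 against E12 comparison asks how progenitors at the ventricular surface differ between these 2 ages. Genes that mark early cortical progenitors were lower at E15. Nr2f1, a transcription factor of area patterning, was at 161 CPM at E15 (428 without the many-gene libraries) and 630.1 at E12, and Igf2bp1, an RNA-binding protein of early progenitors, at 15.9 and 165 CPM. S phase genes were lower as well (Tyms, thymidylate synthase, 213 against 577 CPM; Mcm5, a replicative helicase subunit, 164 against 375 CPM). Genes of late progenitors and of astrocytes were higher in part: Id3, an inhibitor of basic helix-loop-helix factors, was at 38.2 against 1.21 CPM, and Aldh1l1, a folate enzyme of astrocytes, at 50.5 against 2.02 CPM (14.5 without E15 replicate 13). Neuronal genes were higher at E15, with Stmn2, a microtubule regulator of growing axons, at 1517 against 118 CPM (699.8 without the many-gene libraries).

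All 7 measured members of the early temporal list were lower at E15, with a median log2 ratio of -2.06 (-2.42 to -1.49 when single cells were left out), at percentile 0.01 of random lists matched on expression. In the other 49 libraries all 7 were lower too, with a median of -1.45. The late and gliogenic list had 12 members higher and 11 lower at E15, with a median of 0.54 at percentile 99.7. This median was 0.01 without E15 replicate 13 and -0.41 without pool E. Leaving out the many-gene libraries, 19 members were higher and 4 lower, with a median of 0.91 and a list sum of 12046 against 7192 CPM. Ptn, a secreted growth factor, was lower over all cells (1050.5 against 2006 CPM) and higher without the many-gene libraries (3159 CPM at E15). Nfib, a transcription factor of gliogenesis, was lower in both (646 and 1076 against 1207 CPM).

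The apical progenitor list had 15 members lower and 5 higher at E15, with a median log2 ratio of -1.46. After the 16 libraries were left out, the median was -0.59, with 13 lower and 7 higher, while the summed list was at 22071 against 10950.4 CPM. Lhx2, which specifies cortex, was at 177 against 1133 CPM (503 without the many-gene libraries), and Sox3, a neural progenitor factor, at 41.8 against 164 CPM (114 without). Fabp7, a lipid-binding protein of radial glia, went the other way, at 2611 against 1021 CPM (8229.8 without the many-gene libraries). Dbi, a ligand of benzodiazepine receptors and a carrier of acyl-CoA, was at 2430.5 against 1902 CPM.

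The neuronal list had 14 members higher and 6 lower, with a median of 1.63 (0.92 without the many-gene libraries). Tubb3, a neuronal tubulin, was at 1250 against 227 CPM (453 without). Intermediate progenitor genes had a median of -0.35, with 2 of 12 higher. The median was 0.10 without the many-gene libraries and 0.79 as a mean of ratios within pools. The 8 deep-layer genes split evenly at a median of -0.43 (-0.17 without the many-gene libraries; 0.07 without E12 replicate 19; 0.59 within pools). Among them Foxp2, a forkhead factor of corticothalamic neurons, was at 99.0 against 6.07 CPM. Of 9 upper-layer genes 7 were higher (median 0.47; 0.55 without), among them Pou3f1, a POU factor, at 172 against 16.2 CPM, and Lmo4, a LIM-domain cofactor, at 450 against 86.6 CPM (127.6 without).

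Of 42 S phase genes 37 were lower at E15 (median -0.97, percentile 0.0), and 36 were without the many-gene libraries (median -0.89). G2 and M phase genes had 38 members higher and 15 lower (median 0.44), with Cdc20, an activator of the anaphase-promoting complex, at 344 against 44.3 CPM and Hmmr, a spindle protein, at 70.8 against 9.71 CPM. With the 16 libraries left out 27 were higher and 26 lower (median 0.01), and without libraries above 7000 genes the median was -0.16. Of 18 genes of the integrated stress and unfolded protein response 16 were lower (median -1.18; -1.24 without the many-gene libraries), with Hspa5, an endoplasmic reticulum chaperone, at 409.5 against 889.5 CPM. Herpud1, of protein degradation at the endoplasmic reticulum, was at 155 against 366 CPM. Cebpb, a transcription factor, went the other way, at 101 against 6.68 CPM.

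Wnt and Notch lists were lower at E15 over all cells and near 0 without the many-gene libraries, while the FGF and ERK list lay within the range of random lists (percentile 7.31). As a mean of ratios within pools the Wnt, Notch and FGF medians were 0.14, 0.42 and 1.37, so their direction stays open. Ratios within pools rest on few and partly shallow cells, such as the 1 E12 cell of pool H with 10928 reads. A gene without a read in such a cell enters at the pseudocount of 1 CPM, so these ratios can also move with depth. Canonical Wnt genes had 18 of 22 members lower (median -1.06; -0.03 without), with Tcf7l1, a repressor of Wnt targets, at 11.3 against 200.5 CPM. Notch genes had 13 of 17 lower (median -1.01; -0.14 without), with Hes1, a Notch effector, at 97.2 against 547 CPM (327 without). Genes of FGF and ERK signalling had 4 of 7 lower (median -0.77; -0.05 without). Potassium channels and gap junctions had 6 of 9 higher (median 2.45; 1.38 without), with Kcnk2, a two-pore potassium channel, at 68.1 against 0.809 CPM. Gja1, connexin 43, was lower, at 1.41 against 43.7 CPM.

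Among single genes, Pbx3, a TALE homeobox factor (chromosome 2, 34171457 to 34373142, GRCm38), was read in 16 of 26 E15 cells at 118 CPM (115 to 122) and in none of the 20 E12 cells. It was at least 195-fold higher at E15, against a floor of 3 counts over the E12 group (0.607 CPM). Nr4a2, an orphan nuclear receptor of subplate and claustrum neurons (chromosome 2, 57106830 to 57124003), was at 0.854 CPM at E15 (0.584 to 1.21) and 179.5 at E12 (168 to 192). Its log2 ratio was -6.61 (-6.88 to -6.26 over left-out cells), and -6.43 without the many-gene libraries. The other 9 genes taken as higher were Il1a, Gatm, Hist1h1c, Spi1, Pid1, C1qa, Trem2, Isl1 and Ly86, at 94.8 to 227.5 CPM at E15 and at most 1.62 CPM at E12. Il1a, a cytokine, had 3 reads at E12, a CPM ratio of 364 (125 to 1767). In the 2 pools without many-gene libraries the log2 ratios of Il1a and Hist1h1c were -0.26 and -0.42, and those of C1qa and Pid1 were 0.21 and 0.31. Spi1, C1qa, Trem2 and Ly86 are genes of microglia and other myeloid cells. Isl1, a LIM homeobox factor of ventral cells, was at 106.5 CPM with and at 0 CPM without the many-gene libraries. Among the others taken as lower were Boc, a Hedgehog co-receptor, Gja1, Rest, a repressor of neuronal genes, Bst2, which interferon induces, Lix1, Etl4, Ttr and Zfp36l1. Rest was at 4.96 against 116.5 CPM and Bst2 at 14.5 against 281 CPM. Without the many-gene libraries 1 of the 10 higher and 5 of the 10 lower genes met the same rule. Histone Hist1h1c has near-identical family members, so its reads may be shared with them.

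Markers of other cell types differed between the groups. All 13 measured microglia and macrophage genes were higher at E15 (median 5.58, list sum 3308 against 87.8 CPM; 3.80 and 1189.9 CPM without the many-gene libraries). The last sum was 249 CPM without E15 replicate 10, which held 81.9% of its reads. C1qc, a complement subunit, was at 455 against 4.45 CPM (95.7 without the many-gene libraries). All 12 ventral telencephalon and interneuron genes were higher (median 2.97, 2847 against 266 CPM; E12 replicate 19 held 80.6% of the E12 reads). Leaving out the many-gene libraries, 8 of 11 were higher at a median of 0.56, and without libraries above 7000 genes the median was -2.13. Dlx2, a homeobox factor of ventral progenitors, was at 699 against 25.3 CPM (103 without the many-gene libraries). The 5 erythroid genes had a median of -0.08 (-1.22 without E15 replicate 6; 1.16 without the many-gene libraries). Of the other lists 1 or 2 members were measured. Ttr, a choroid plexus transthyretin, was at 13.6 against 119.6 CPM, and Egfl7, an endothelial gene, at 2.99 against 18.4 CPM. Olig2, an oligodendrocyte factor, was at 11.05 against 2.23 CPM. Col1a2, a fibroblast collagen, was at 5.84 CPM at E15 and had no read at E12 (at least 9.63-fold higher).

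The transplanted against E15 comparison asks what differs in E15 progenitors after time in a younger brain. Late progenitor genes were lower in transplanted cells. Tnc, the matrix protein tenascin C of late radial glia (chromosome 4, 63959785 to 64047015), was read in 2 of 19 transplanted cells at 0.236 CPM (0.0487 to 0.689) and in 14 of 26 E15 cells at 61.8 CPM (59.3 to 64.3). Its log2 ratio was -5.67 (-5.85 to -5.02 over left-out cells), and the CPM ratio of E15 to transplanted cells was 262 (89.5 to 1270.5). Cst3, a cysteine protease inhibitor, was at 507 against 1202 CPM. Igf2bp1, of early progenitors, was at 33.7 against 15.9 CPM, a log2 ratio of 1.04 that turned to -0.84 without libraries above 7000 genes. Embryonic globins were higher, with Hbb-y at 1692 against 442 CPM. E15 replicate 6 alone held 98.7% of the E15 reads of Hbb-y, and without it the E15 level was 5.92 CPM. The log2 ratio ran from 0.77 to 7.93 over left-out cells.

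The late and gliogenic list had 20 members lower and 2 higher, with a median log2 ratio of -1.05 (-1.35 to -0.57 over left-out cells) at percentile 0.0 and a list sum of 3050 against 6850 CPM. After the 16 libraries were left out, 19 were lower and 4 higher, with a median of -1.58 and sums of 4749 against 12046 CPM. Hopx, a homeodomain protein of outer radial glia, was at 7.54 against 183 CPM there. Apoe, an apolipoprotein of glia and microglia, was at 351 against 1144 CPM over all cells and at 707 against 447 CPM without the many-gene libraries. Slc1a2, a glutamate transporter of astrocytes (chromosome 2, 102658659 to 102790784), went the other way, at 20.2 against 2.43 CPM.

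The early temporal list had 6 of 7 members higher, with a median of 0.92 at percentile 99.995. With the 16 libraries left out 5 were higher and 3 lower (median 0.73) while the list sum was lower (387 against 574 CPM), and as a mean of ratios within pools the median was -0.26. Nr2f1 was at 265 against 161 CPM over all cells and at 161 against 428 CPM without the many-gene libraries. The apical progenitor list had 9 members higher and 10 lower (median -0.04), and 5 and 14 without the many-gene libraries (median -0.51). Transplanted replicate 19, the deepest of those below 8000 genes, weighed on this list, with a median of -0.84 when it was left out.

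Neuronal genes split 13 and 7 (median 0.04; 0.09 without the many-gene libraries; -0.85 without libraries above 7000 genes), with Stmn2 at 1113 against 1517 CPM and Tubb3 at 1148 against 1250 CPM. Intermediate progenitor genes had a median of -0.22 (-1.18 without), deep-layer genes -0.31 (-0.43 without) and upper-layer genes -0.07 (0.15 without). Lmo4 was at 127.5 against 450 CPM and Pou3f1 at 54.9 against 172 CPM. Of 42 S phase genes 26 were higher (median 0.27), and 30 without the many-gene libraries (median 0.77). The S phase median was -0.05 without transplanted replicate 19 and -0.45 as a mean of ratios within pools. Rrm2, a ribonucleotide reductase subunit, was at 425 against 255 CPM. G2 and M phase genes had 37 of 53 lower (median -0.14), while without the many-gene libraries 36 were higher and 16 lower (median 0.50). G1 and cell cycle exit genes had 13 of 20 lower (median -0.54; 0.02 without), with Ccnd2, a D-type cyclin, at 1776 against 2977 CPM.

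Of 18 stress response genes 10 were higher in transplanted cells (median 0.12; -0.71 as a mean of ratios within pools), and 12 of 17 without the many-gene libraries (median 0.83). Chac1, a glutathione-degrading enzyme induced by the integrated stress response (chromosome 2, 119351229 to 119354381), was at 138.5 CPM (132 to 145) in 15 of 19 transplanted cells and at 24.97 CPM (23.4 to 26.6) in 15 of 26 E15 cells. Its log2 ratio was 2.42 (1.99 to 2.82 over left-out cells), and 3.53 without the many-gene libraries. Atf4, the main factor of that response, was at 465 against 348 CPM. Immediate-early and heat shock genes had 14 of 17 lower (median -0.72), among them Egr1 (6.37 against 48.1 CPM) and Fos (11.8 against 55.3 CPM), both induced by stimulation. In the other 49 libraries 11 were higher and 6 lower (median 0.25), while Egr1 and Fos were at 5.17 and 5.39 against 43.9 and 82.4 CPM.

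Wnt genes had a median of -0.18 (-0.87 without the many-gene libraries), with Sfrp1, a secreted Wnt antagonist, at 179 against 367 CPM. Notch genes were at -0.29 (-0.81 without) and genes of FGF and ERK signalling at -0.20 (-0.01 without; 0.44 with a limit of 7000 genes). Potassium channels and gap junctions had 7 of 9 lower (median -0.72; -1.29 without), with Kcne1l, a potassium channel subunit, at 13.6 against 67.8 CPM. The sign of this median turned on mean CPM per cell (0.65), on thinned counts (0.83), on mean CPM without the many-gene libraries (1.09) and with a limit of 7000 genes (0.60). Cholesterol synthesis genes had 14 of 22 lower (median -0.34), and 19 of 22 without the many-gene libraries (median -0.88).

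The other 8 genes taken as higher were Xylt1, Ddx59, Hba-x, Unc119, Hbb-y, Jmjd6, Fnip2 and Igf2bp1, at log2 ratios of 1.01 to 2.39. The other 9 taken as lower were Ccl4 and Ccl3, chemokines of activated microglia, P2ry12, a microglial purine receptor, Scrg1, Slco1c1, a thyroid hormone transporter, Loxl1, Fgd2, Cryba4 and Hebp1. Ccl4 was at 3.93 against 663 CPM and P2ry12 at 3.70 against 85.4 CPM. The log2 ratio of Ccl4 went from -7.07 to -0.15 on mean CPM without the many-gene libraries. In the 2 pools with no such library that of Ccl3 went from -3.71 to 0.12 and that of Cryba4 from -3.39 to -0.18. Slco1c1 and Loxl1 had 1 and 2 reads in transplanted cells, with CPM ratios of 264 (47.2 to 10426) and 172 (47.6 to 1425). Without the many-gene libraries 7 of the 10 higher and 5 of the 10 lower genes met the same rule.

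All 13 microglia and macrophage genes were lower in transplanted than in E15 cells (median -1.58), while without the many-gene libraries 9 were higher (median 1.19). Among the 14 transplanted libraries left, the sum reached 25413.5 CPM in replicate 8 and 6994 CPM in replicate 18, with a median of 336 CPM. The many-gene libraries themselves stood at median sums of 29.5 CPM in transplanted and 3366 CPM in E15 cells. Of 12 ventral genes 10 were lower (median -0.62), and without the many-gene libraries 9 were higher (median 1.35). All 5 erythroid genes were higher (median 2.63; 2.81 without the many-gene libraries), with a list sum of 15773 against 2636 CPM (3250 without transplanted replicate 19, and 1085 without E15 replicate 6). This median was 0.10 without transplanted replicate 19 and 4.07 without E15 replicate 6. Adult globins Hbb-bs (7588 against 1226 CPM; 652 without transplanted replicate 19) and Hba-a1 (3733 against 580.5 CPM; 623 without it) have near-identical copies, so reads may be shared between them. Ttr was at 18.7 against 13.6 CPM and Col1a2 at 5.11 against 5.84 CPM. Olig2 was at 12.3 against 11.05 CPM.

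**Figure D3:**
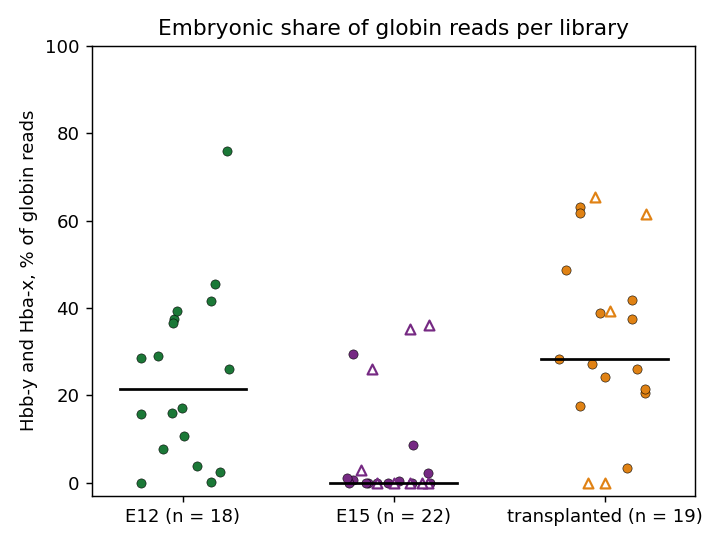
Percent of globin reads that came from the embryonic globins Hbb-y and Hba-x in each library with at least 20 globin reads, with triangles for libraries above 8000 genes and lines for the medians. The median was 21.5% in E12, 0% in E15 and 28.2% in transplanted libraries.

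The transplanted against E12 comparison asks what still differs from cells of the host's age. The median of neuronal genes was higher and that of apical progenitor genes lower in transplanted cells, as in E15 cells. Stmn2 was at 1113 against 118 CPM, Tubb3 at 1148 against 227 CPM and Stmn3, another microtubule regulator, at 1157 against 130.1 CPM. Ttyh1, a membrane protein of progenitors, was at 83.3 against 609 CPM and Emx2, a homeobox factor of dorsal cortex, at 18.6 against 146 CPM. Notch and cholesterol synthesis genes were lower, with Hes1 at 98.3 against 547 CPM and Msmo1, a sterol oxidase, at 55.1 against 385 CPM. Wnt genes were lower over all cells, with Sfrp1 at 179 against 926 CPM. Their median was 0.22 as a mean of ratios within pools, so the Wnt direction stays open.

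The apical progenitor list had 17 members lower and 3 higher (median log2 ratio -1.47), and 14 and 6 without the many-gene libraries (median -0.66). Its sum went from 8160 against 10950.4 CPM over all cells to 16457 CPM without the many-gene libraries, and to 8766 CPM when transplanted replicate 19 was left out as well. On mean CPM per cell without the many-gene libraries the sums were 11032 and 11451 CPM, so the sums gave no direction. Fabp7 was at 3038 against 1021 CPM, and at 1059 CPM without transplanted replicate 19. The early temporal list had 6 of 8 lower (median -1.16; -1.17 without the many-gene libraries; -0.46 without pool E), with Nr2f1 at 265 against 630.1 CPM and Igf2bp1 at 33.7 against 165 CPM. The late and gliogenic list had 16 of 23 lower (median -0.89), with Ptn at 437 against 2006 CPM, Nfib at 309.7 against 1207 CPM and Nfix, another nuclear factor I protein, at 102 against 536 CPM. After the 16 libraries were left out, its median was -0.11, and 0.04 on mean CPM per cell.

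The neuronal list had 14 members higher and 6 lower (median 1.45; 0.95 without the many-gene libraries). Deep-layer genes had a median of -0.27 (-0.51 without). Bcl11b of that list, a factor of subcerebral neurons, went the other way, at 252 against 53.6 CPM. Upper-layer genes had a median of 0.60 (0.68 without). Intermediate progenitor genes had 8 of 12 lower (median -0.82; -1.43 without; 0.13 within pools). Of 42 S phase genes 37 were lower (median -0.76), and 23 without the many-gene libraries (median -0.14). G2 and M phase genes had 35 of 53 higher (median 0.43; 0.48 without; -0.025 on thinned counts), with Cenpa, the centromeric histone, at 381 against 132.5 CPM. Stress response genes had 15 of 18 lower (median -0.84; -0.27 without; 0.43 as a mean of ratios within pools), with Hspa5 at 323 against 889.5 CPM. Notch genes had 13 of 16 lower (median -1.60; -1.33 without), Wnt genes 16 of 23 (median -1.04; -1.04 without; 0.22 within pools) and cholesterol synthesis genes 20 of 22 (median -0.92; -0.88 without). FGF and ERK genes had a median of -1.34 (-0.25 without) and G1 genes -0.82 (-0.15 without; 0.12 within pools).

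The 10 genes taken as higher were Ap1s2, Rusc1, Actl6b, Sst, Lancl2, Zfyve19, Rps4l, Rab3c, Smpd1 and Ly86. Ap1s2, of vesicle sorting, was at 106 against 1.01 CPM. Sst, the neuropeptide somatostatin of interneurons, was at 145 against 1.62 CPM. Rusc1 was read in 8 of 19 transplanted cells at 47.9 CPM (44.2 to 51.9) and in no E12 cell, at least 78.9-fold higher. Lancl2 and Zfyve19 had 3 reads each and Rab3c 2 reads at E12, with CPM ratios of 97.6 (33.3 to 474), 96.1 (32.8 to 467) and 142 (39.1 to 1174). Rps4l is a near-copy of a ribosomal protein gene, so its reads may be shared. The 10 taken as lower were Etl4, Jam3, Ttyh1, Nog, Zfp36l1, Efnb1, Emx2, Msmo1, Tmem216 and Ldlrad3. Etl4 was at 4.56 against 189.6 CPM and Nog, a secreted BMP antagonist, at 10.3 against 81.7 CPM. With the 16 libraries left out 1 of the higher and 7 of the lower genes met the same rule.

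All 11 measured microglia and macrophage genes were higher in transplanted than in E12 cells (median 4.10; 4.23 without the many-gene libraries), with C1qb, a complement subunit, at 237 against 4.45 CPM. Outside the many-gene libraries, transplanted replicates 8 and 18 had the highest sums of this list, as given above. Of 12 ventral genes 11 were higher (median 3.38, or 3.40 with the member at 0 E12 reads at its bound; 2.73 without the many-gene libraries), with Dlx1 at 431 against 36.6 CPM. In the deposited values, from which the submitters had removed 2 directions over cells, the median differences of these lists were -0.09 and -0.12 on the log10 scale. The erythroid median was 2.23 (3.68 without the many-gene libraries), and -0.52 without transplanted replicate 19. Ttr was at 18.7 against 119.6 CPM and Egfl7 at 2.75 against 18.4 CPM. Olig2 was at 12.3 against 2.23 CPM and Col1a2 at least 8.42-fold higher.

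**Figure D4:**
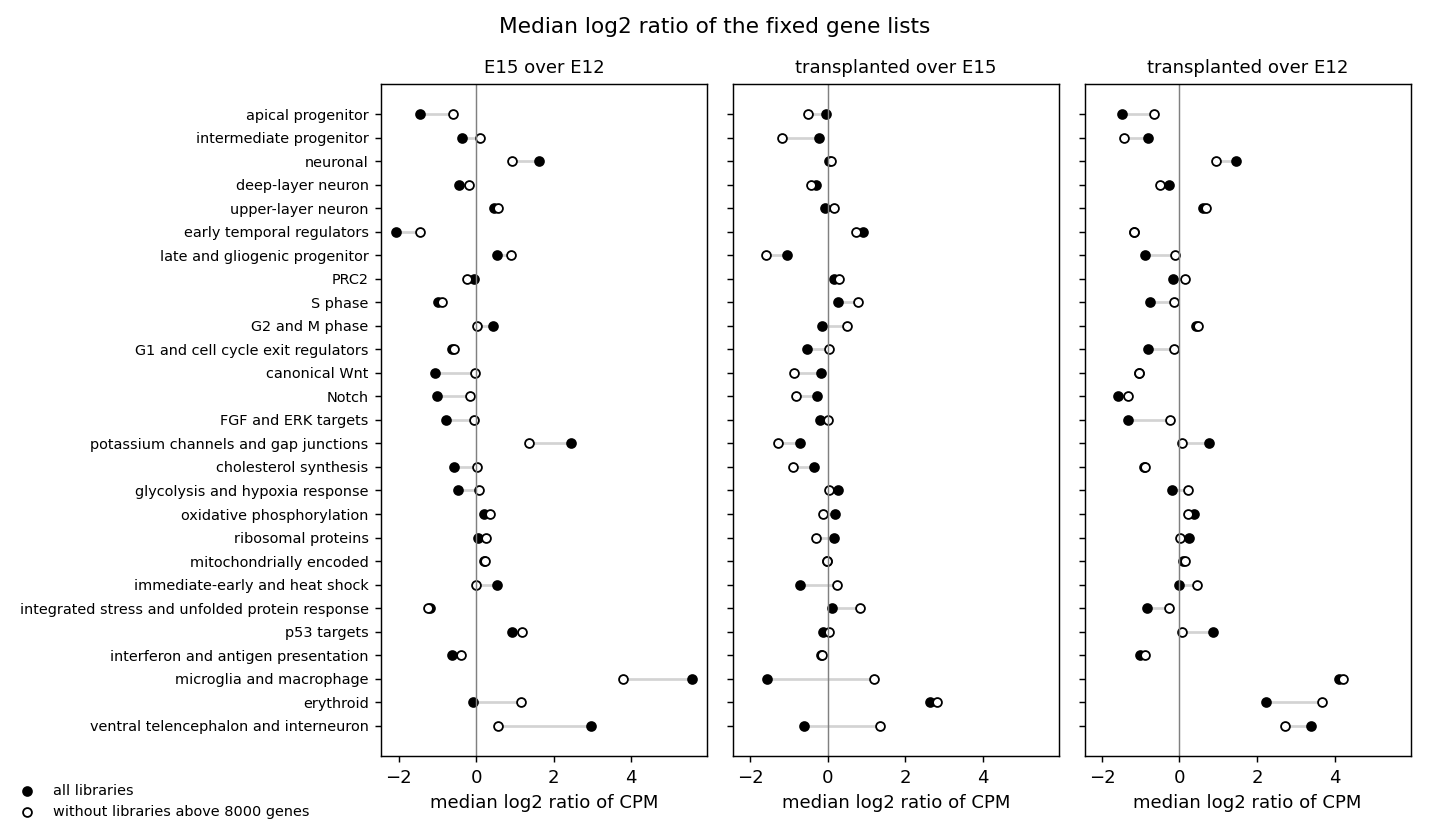
Median log2 ratio of fixed gene lists in the 3 comparisons, black for all libraries and open for values without the 16 libraries above 8000 genes. Lists with few or no measured members are not drawn. The late and gliogenic list lies at -1.05 and -1.58 in transplanted over E15 cells.

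Whether transplanted cells lay nearer to E12 or to E15 was asked in 3 ways. The 200 genes most higher at E15 were chosen in pools A to D and measured in E to H, then the reverse. Their median E15 over E12 log2 ratio was 5.51 in the choosing cells and 1.47 in the cells held out, against 1.14 for transplanted over E12. The position, the ratio of these, was 0.78 where E12 is 0 and E15 is 1 (0.60 to 0.90 over 100 random splits; 0.63 to 0.87 over left-out cells). In the other 49 libraries the held-out difference was 0.06, so no position was taken. The 200 genes most higher at E12 had a held-out median of -0.14 and 0.15 for transplanted over E12, and no position was taken for them either. The transplanted cells differed from E12 cells in the E15-high genes by most of the held-out age difference, and this rested on the many-gene libraries.

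By correlation with mean profiles of 15 cells, 19 of 20 E12 cells (95%, 75.1 to 99.9) and 8 of 26 E15 cells (30.8%, 14.3 to 51.8) were nearer to the E12 profile. Of the transplanted cells 9 of 19 were (47.4%, 24.4 to 71.1), and 3 of 19 with a rank correlation (15.8%, 3.38 to 39.6). Against the same profiles 0 of 11 E15 and 0 of 5 transplanted many-gene libraries were nearer to E12. Among the other libraries 8 of 15 E15 cells (53.3%) and 9 of 14 transplanted cells (64.3%) were. With the many-gene libraries left out of the profiles too, 16 of 20 E12 cells and 1 of 15 E15 cells (6.67%, 0.169 to 31.9) were nearer to E12. Of the transplanted cells 8 of 14 were (57.1%, 28.9 to 82.3). With a limit of 7000 genes 0 of 12 E15 cells (0%, 0 to 26.5) and 9 of 13 transplanted cells (69.2%, 38.6 to 90.9) were, and with 9000 genes 1 of 17 (5.88%, 0.149 to 28.7) and 7 of 17 (41.2%, 18.4 to 67.1). These limits were tried after the data had been seen, and the intervals treat cells as independent, so no difference between the groups was read from them.

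Across 10315 genes, log2 ratios of transplanted over E15 and of E12 over E15 cells correlated at 0.255 (covariance 0.340), where genes are not independent replicates. Both ratios share the E15 cells, which alone gives a positive value. With the E15 cells split into 2 sets, 1 for each ratio, the correlation was 0.123 (covariance 0.180). Groups without a difference drawn from the E15 cells gave 0.422 (covariance 0.141). Without the many-gene libraries the values were 0.348, -0.01 with split cells and 0.529 in groups without a difference. The covariance with split cells, in which no shared cells enter, was positive over all libraries and -0.06 without the many-gene libraries.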

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

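The settings without the libraries above 8000, 7000 or 9000 genes, and those in the 2 pools without libraries above 8000 genes, were added after the data had been seen, and the others were chosen before the data were examined. No paired analysis was possible because the replicate numbers follow the order of deposition within each group and pair no cells. Pools hold cells of 2 or 3 groups, and the comparison within them is given below as the mean of ratios within pools. Pool H holds 1 E12 cell and pool E 1 transplanted cell, so these ratios can also move with the depth of single cells. Among the leading results, which are the 3 progenitor lists, the positions, the cells nearer to a profile and the relation of ratios, 862 values under chosen settings lay within the spread, 74 moved by more and 2 changed the sign of a called result. A list was called where its median lay outside 95% of random lists. Under the added settings the counts were 19, 43 and 1. Changes of sign, whether or not the result was called, numbered 25 under chosen and 3 under added settings. The 3 progenitor lists were taken as leading after the medians of all lists had been seen. For the other lists 4088 values lay within the spread, 1045 moved and 22 changed the sign of a called list under chosen settings, and 130, 235 and 44 under added ones. All changes of sign of these lists numbered 181 and 106. For named genes the counts were 845, 295 and 0 under chosen settings, and 82, 210 and 8 under added ones, where 7 changed sign and 1 was at 0. Why a value moved was not tested in this part.

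For E15 over E12 cells the values that moved or changed sign are the log2 ratio of a gene or the median log2 ratio of a list. On mean CPM per cell the value was -0.87 for apical progenitor genes and -0.020 for immediate-early genes. On thinned counts the value was -0.88 for apical progenitor genes and -0.22 for immediate-early genes. At a pseudocount of 5 CPM the value was -1.20 for apical progenitor genes. As a mean of the ratios within pools the value was -1.23 for apical progenitor genes, -1.37 for early temporal genes, 0.92 for late and gliogenic genes, 0.14 for Wnt genes and 0.42 for Notch genes. Without the libraries above 8000 genes the value was -0.59 for apical progenitor genes, -1.45 for early temporal genes, 0.91 for late and gliogenic genes and -0.27 for Isl1. On mean CPM without the libraries above 8000 genes the value was -0.47 for apical progenitor genes, 1.10 for late and gliogenic genes, -0.70 for immediate-early genes and -0.40 for Isl1. In the 2 pools with no such library the value was -0.077 for apical progenitor genes, -0.70 for early temporal genes, 1.10 for late and gliogenic genes, 0.062 for Wnt genes, -0.26 for Il1a, -0.42 for Hist1h1c and 0 for Isl1. With a limit of 7000 genes the value was -0.66 for apical progenitor genes, 1.17 for late and gliogenic genes, -0.16 for G2 and M phase genes, 0.13 for Wnt genes, -2.13 for ventral genes and -0.27 for Isl1. With a limit of 9000 genes the value was -0.82 for apical progenitor genes, -1.18 for early temporal genes, 0.83 for late and gliogenic genes and -0.0031 for immediate-early genes. At a filter of 20 CPM the value was 0.18 for late and gliogenic genes. With single cells or pools left out, apical progenitor genes ran from -1.99 without pool E to -1.12 without pool B. Early temporal genes ran from -2.49 without pool A to -1.49 without E12 replicate 5. Late and gliogenic genes ran from -0.41 without pool E to 0.65 without E12 replicate 6.

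For transplanted over E15 cells the late and gliogenic median stayed negative under every setting tried, while other lists changed sign. On mean CPM per cell the value was -0.45 for apical progenitor genes and 0.65 for potassium channels. On thinned counts the value was -0.76 for apical progenitor genes, -1.26 for late and gliogenic genes and 0.83 for potassium channels. With no filter above 1 count the value was -0.15 for apical progenitor genes. Without the libraries above 8000 genes the value was -0.51 for apical progenitor genes, -1.58 for late and gliogenic genes, 0.50 for G2 and M phase genes, 0.022 for G1 genes, -0.11 for oxidative phosphorylation, -0.29 for ribosomal proteins, 0.25 for immediate-early genes, 1.19 for microglia genes and 1.35 for ventral genes. On mean CPM without the libraries above 8000 genes the value was -0.66 for apical progenitor genes, 0.22 for G2 and M phase genes, 0.056 for G1 genes, 1.09 for potassium channels, -0.015 for ribosomal proteins, 0.54 for immediate-early genes, 1.90 for microglia genes and 0.90 for ventral genes. In the 2 pools with no such library the value was -0.74 for apical progenitor genes, 0.17 for early temporal genes, -1.94 for late and gliogenic genes, 0.64 for G2 and M phase genes, 0.011 for G1 genes, -0.027 for glycolysis, -0.099 for oxidative phosphorylation, -0.39 for ribosomal proteins, 0.41 for immediate-early genes, 3.40 for microglia genes, 2.98 for ventral genes and 0.12 for Ccl3. With a limit of 7000 genes the value was -0.73 for apical progenitor genes, 1.57 for early temporal genes, -1.22 for late and gliogenic genes, 0.11 for G2 and M phase genes, 0.60 for potassium channels, -0.052 for glycolysis, -0.073 for ribosomal proteins, 0.35 for immediate-early genes, 1.13 for microglia genes, 2.97 for ventral genes and -0.84 for Igf2bp1. With a limit of 9000 genes the value was -0.84 for apical progenitor genes, -1.73 for late and gliogenic genes, 0.34 for G2 and M phase genes, -0.037 for glycolysis, 0.11 for immediate-early genes and 0.26 for microglia genes. At a pseudocount of 5 CPM the value was 0.57 for early temporal genes. As a mean of the ratios within pools the value was -0.26 for early temporal genes, -1.30 for late and gliogenic genes, -0.45 for S phase genes, -0.28 for oxidative phosphorylation and -0.092 for ribosomal proteins. With single cells or pools left out, apical progenitor genes ran from -0.84 without transplanted replicate 19 to 0.36 without pool E. Early temporal genes ran from 0.51 without transplanted replicate 19 to 1.05 without transplanted replicate 14. Late and gliogenic genes ran from -1.36 without pool G to -0.41 without pool E. S phase genes ran from -0.097 without pool A to 0.42 without pool C. G2 and M phase genes ran from -0.31 without transplanted replicate 19 to 0.062 without pool C. Ribosomal proteins ran from -0.046 without transplanted replicate 14 to 0.35 without pool A.

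For transplanted over E12 cells, among the 3 leading lists, the late and gliogenic median moved most often. On mean CPM per cell the value was -0.90 for apical progenitor genes, -0.059 for late and gliogenic genes and 0.091 for interferon genes. On thinned counts the value was -0.88 for apical progenitor genes, -0.33 for late and gliogenic genes, -0.025 for G2 and M phase genes and 0.16 for interferon genes. Without the libraries above 8000 genes the value was -0.66 for apical progenitor genes and -0.11 for late and gliogenic genes. On mean CPM without the libraries above 8000 genes the value was -0.68 for apical progenitor genes, 0.038 for late and gliogenic genes, -0.011 for G2 and M phase genes and 0.30 for interferon genes. In the 2 pools with no such library the value was -0.77 for apical progenitor genes, -0.0017 for late and gliogenic genes, 0.043 for S phase genes and 0.24 for FGF and ERK genes. With a limit of 7000 genes the value was -0.55 for apical progenitor genes, -0.38 for late and gliogenic genes and -0.11 for G2 and M phase genes. At a filter of 20 CPM the value was -1.75 for early temporal genes. As a mean of the ratios within pools the value was -0.30 for late and gliogenic genes, 0.22 for Wnt genes and 0.43 for stress response genes. With single cells or pools left out, apical progenitor genes ran from -1.87 without transplanted replicate 19 to -1.20 without pool D. Early temporal genes ran from -1.37 without pool A to -0.46 without pool E. Late and gliogenic genes ran from -1.30 without pool A to -0.56 without pool D. Erythroid genes ran from -0.52 without transplanted replicate 19 to 2.72 without pool H.

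Lists whose main median lay within 95% of random lists, or had too few members to be placed among them, took both signs as well, and for these the median furthest on the other side of 0 is given. In E15 over E12 cells it was 0.79 for intermediate progenitor genes, 0.59 for deep-layer genes, 0.59 for G1 genes, 1.37 for FGF and ERK genes, 0.53 for cholesterol synthesis genes and 1.02 for interferon genes within pools. It was 0.39 for PRC2 genes, 0.35 for glycolysis, 1.35 for erythroid genes and 1.53 for oligodendrocyte genes in the 2 pools with no library above 8000 genes, and -0.059 for ribosomal proteins and -0.026 for mitochondrially encoded genes on mean CPM per cell. In transplanted over E15 cells it was 0.36 for apical progenitor genes and 0.28 for intermediate progenitor genes without pool E. It was -0.85 for neuronal genes, 0.44 for FGF and ERK genes, 0.87 for mitochondrially encoded genes and 1.56 for fibroblast genes with a limit of 7000 genes, and 0.89 for deep-layer genes in the 2 pools with no library above 8000 genes. It was 0.18 for upper-layer genes on mean CPM without the libraries above 8000 genes, and -0.10 for PRC2 genes without transplanted replicate 19. It was 0.16 for Wnt genes and 0.057 for Notch genes without E15 replicate 13, and -0.71 for stress response genes within pools. It was 0.063 for p53 targets without pool F, and 1.002 for interferon genes on thinned counts. It was -1.29 for choroid plexus genes without transplanted replicate 11. In transplanted over E12 cells it was 0.13 for intermediate progenitor genes, 0.63 for PRC2 genes, 0.12 for G1 genes and 0.17 for endothelial genes within pools. It was 0.15 for deep-layer genes, 0.24 for glycolysis and 0.66 for immediate-early genes in the 2 pools with no library above 8000 genes, and -1.01 for potassium channels and -1.75 for oligodendrocyte genes at a filter of 20 CPM. It was -0.036 for ribosomal proteins on mean CPM without the libraries above 8000 genes, and -0.027 for mitochondrially encoded genes without transplanted replicate 11. It was -0.53 for p53 targets with a limit of 7000 genes.

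In the position of transplanted cells, the held-out E15 over E12 median of the E15-high genes was 0.063 without the libraries above 8000 genes and 0.27 as a mean of 100 random splits of the same libraries. The transplanted over E12 median of these genes was 1.40 with 100 genes, 0.18 without the libraries above 8000 genes and 0.41 as a mean of random splits without them. For the E12-high genes the held-out median was -0.28 with 100 genes, -0.37 as a mean of random splits and -0.48 in random splits without the libraries above 8000 genes. Their transplanted over E12 median was -0.071 with 500 genes, -0.15 as a mean of random splits, -0.17 on summed counts, -0.098 without the libraries above 8000 genes and -0.11 in random splits without them.

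Of E12 cells 75% were nearer to the E12 profile with a limit of 9000 genes. Of E15 cells 6.67% were nearer to E12 without the libraries above 8000 genes, 0% with a limit of 7000 genes and 5.88% with a limit of 9000 genes. Of transplanted cells 15.8% were nearer to E12 with a rank correlation. The correlation of the ratios that share E15 cells was 0.12 with split E15 cells, 0.34 on mean CPM per cell and 0.35 without the libraries above 8000 genes.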

Other observations

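All tests of explanations in this part were chosen after the results had been seen. In E15 over E12 cells the median log2 ratio of glycolysis and hypoxia genes was -0.47 (0.07 without the libraries above 8000 genes) and that of cholesterol synthesis genes -0.57 (0.02 without; 0.53 as a mean of ratios within pools). Oxidative phosphorylation genes were at 0.20 (0.37 without), ribosomal proteins at 0.06 (0.25 without) and mitochondrially encoded genes at 0.21 (0.24 without). In transplanted over E15 cells glycolysis was at 0.25 (0.02 without), oxidative phosphorylation at 0.19 (-0.11 without; -0.28 within pools), ribosomal proteins at 0.17 (-0.29 without; -0.092 within pools) and mitochondrially encoded genes at -0.01 (-0.03 without; 0.87 with a limit of 7000 genes). In transplanted over E12 cells these lists were at -0.20, 0.36, 0.24 and 0.08 (0.23, 0.22, 0.01 and 0.13 without).

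Genes of PRC2, the Polycomb complex that methylates histone H3, were at -0.05 in E15 over E12 (-0.23 without the libraries above 8000 genes), 0.17 in transplanted over E15 (0.30 without) and -0.16 in transplanted over E12 cells (0.13 without; 0.63 within pools). Ezh2, its methyltransferase, was at 334 CPM in transplanted and 239.8 CPM in E15 cells. G1 and cell cycle exit genes were at -0.62 in E15 over E12 cells (-0.57 without; 0.59 as a mean of ratios within pools). Immediate-early and heat shock genes were at 0.54 in E15 over E12 (0.01 without; -0.020 on mean CPM per cell; -0.22 on thinned counts) and at -0.02 in transplanted over E12 cells (0.46 without). For p53 targets the medians were 0.94, -0.13 and 0.86 in the 3 comparisons (1.196, 0.03 and 0.08 without), and the last was -0.53 with a limit of 7000 genes. Interferon and antigen presentation genes were at -0.63, -0.17 and -1.01 (-0.39, -0.14 and -0.88 without). The first was 1.02 within pools and the second 1.002 on thinned counts. The last of these turned to 0.091 on mean CPM per cell, 0.16 on thinned counts and 0.30 on mean CPM without the libraries above 8000 genes. Potassium channels and gap junctions were at 0.75 in transplanted over E12 cells (0.06 without; -1.01 at a filter of 20 CPM).

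Most of the 16 libraries above 8000 genes carried genes of other cell types beside progenitor genes. Ventral genes summed to 939 CPM or more in 15 of them (110 CPM in transplanted replicate 14), and microglial genes to 715 CPM or more in 13. In the other 3, all transplanted, the microglial sums were 3.03, 7.10 and 29.5 CPM. Deeper sequencing was argued against, since their median at equal depth was 5777.5 genes against 2977.5 in the others (90th percentile 4756). Reads leaking within a pool were argued against, since other libraries of the same pools held 1.77% of their ventral level and 3.77% of their microglia level. RNA of more than one cell type in a library was looked at through 2 lists. Of the 16, 12 had reads of at least 3 ventral and 3 microglia genes at equal depth, as had 9 of 42 others. The 9 were 1 of 17 E12, 4 of 13 E15 and 4 of 12 transplanted libraries. Values without the 16 libraries therefore still include such libraries, more often in the E15 and transplanted groups. The 16 libraries were chosen for many genes and detected more at equal depth. They would hold members of most lists more often, so the count of 12 cannot decide. RNA of more than one cell type stays open as the source, as does the age of the cells, which was not tested. In the pools with such libraries 0 of 13 E12 libraries exceeded 8000 genes (at most 24.7%). Of the E15 and transplanted libraries there, 16 of 33 did (at least 30.8%). This share was raised by taking only pools that hold such libraries. Over all pools 0 of 20 E12, 11 of 26 E15 and 5 of 19 transplanted libraries did.

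The late and gliogenic list was lower in transplanted than in E15 cells. Libraries above 8000 genes as the whole cause were argued against, with a median of -1.58 without them (SD of random lists 0.193). Depth was argued against, with -1.26 on thinned counts (SD 0.167). The SDs in this paragraph are over random gene lists and do not measure variation between cells or pools. Over all libraries the median reached -0.41 when pool E was left out. Fewer progenitors among the transplanted cells may contribute, and this stays open. The late median lay -1.08 from the apical median (SD 0.264), while on summed mean CPM the late list was at 6988 against 12576 (log2 -0.85) and the apical list at 11032 against 23656 (log2 -1.10). An effect of the younger host, which the design names, stays among the open explanations and was not tested apart from handling and time after transplantation.

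Embryonic globins were read in more transplanted than E15 libraries (Hbb-y in 17 of 19 and 11 of 26). Depth was argued against: E15 libraries were deeper and not shallower (medians 998630 and 166134 reads). At equal depth 4 of 24 E15 libraries (4.74 to 37.4%) and 15 of 17 transplanted libraries (63.6 to 98.5%) had a read, 71.6 percentage points apart. Without the libraries above 8000 genes 4 of 13 and 12 of 12 had one. Total globin differed too, at medians of 116 CPM in E15 and 4698 CPM in transplanted libraries. A missing read of Hbb-y at equal depth can therefore reflect less globin of any kind. Exchanged labels between E15 and transplanted libraries may play a part: 4 E15 libraries had over 20% embryonic globin (25.95 to 36.2%), and 2 transplanted libraries had 0%. Of these, 3 of the 4 E15 libraries and both transplanted libraries exceeded 8000 genes. Their shares rest on few reads: 131, 221 and 219 globin reads in the 3 E15 libraries, and 29 and 30 in the transplanted ones. These were 25.2 to 54.0 CPM, against a median of 4698 CPM in transplanted libraries. Under 5% lay 17 of 22 E15 libraries, and above 20% lay 15 of 19 transplanted but only 9 of 18 E12 libraries. E12 replicate 6 was at 0% of 607 globin reads, so the share of a single library does not settle its age or label. The remaining E15 library above 20%, replicate 6, had 60729 globin reads and held 98.7% of the E15 reads of Hbb-y. Blood RNA of the host's age could give the transplanted median of 28.2% (21.5% at E12, 0% at E15), yet pooled shares were 20.3, 18.4 and 11.5% in E12, E15 and transplanted cells. Without the library with most globin reads of each group they were 24.6, 0.641 and 53.6%, so exchanged labels and blood RNA both stay open.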
